A study of Mus musculus with 25 samples.

How the data were processed

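MicroRNAs were measured in total RNA from snap-frozen mouse mammary tissue of the FVB strain, extracted with a column kit, labelled with Cy3 and hybridised to one-colour Agilent mouse miRNA arrays, per the labels' protocols. The 25 arrays held 2 pools of normal mammary gland, 7 tumours of mice with a Met transgene driven by the mouse mammary tumour virus promoter (Met), 8 tumours of mice with that transgene and a conditional deletion of 1 Trp53 allele (MetTrp53), and 8 tumours of mice with the Trp53 deletion alone (Trp53). Groups, pathology and parity were taken from the labels. Replicates were numbered in accession order, so a number only names a sample. The labels do not say that every tumour came from a different animal, and 2 pairs of Trp53 tumours share a number in their titles, so p-values measure the spread between these samples.

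The deposited scanner files hold intensity values of single spots made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal is background-subtracted and spatially detrended by that software, and it is not normalised between arrays. The authors also deposited a table of log2 values per spot, which per the submitters' processing notes involved RMA, with no role or version given in the sources used here. Set against the scanner values of the same spots, its columns follow log2 intensity, with an offset that differs from array to array. The column medians of that table lay between 1.72 and 1.91. How its values were centred is not known.

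Each array held 49324 spots, with 40 spots for each of 1122 mouse miRNAs and for 57 viral miRNAs, and 784 of the mouse miRNAs had 2 different probes. The processed signal was divided by the 75th percentile over the 221 probes that were well above background on all 25 arrays. A floor of 0.0219 of that percentile was then set and log2 taken, so that the lowest printed level is 3.62. Spots marked as outliers by the scanner software were left out, spots of a probe were averaged, and probes of a miRNA were averaged. A miRNA was tested if it was detected on at least 7 tumour arrays or on both normal arrays, which kept 330 miRNAs. One kept only through the normal arrays leans towards a lower value in tumours, and one kept only through tumour arrays towards a higher value. The split into higher and lower calls against normal may therefore depend in part on this filter. Of all mouse miRNAs, 160 were detected on all 25 arrays and 669 on none. The arrays detected between 220 and 334 mouse miRNAs, and between 14 and 21.9 percent of mouse spots were well above background. The scaling percentile ranged from 276.1 to 927.7 intensity units, a 3.36-fold range.

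Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 25 arrays in 1 model with 4 groups, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were tumours against normal (the mean of the 3 genotypes minus normal), each genotype against normal, the 3 pairs of genotypes, a moderated F-test over the genotypes, and spindloid against other stated pathology in 22 tumours with genotype as a covariate. All comparisons with normal share the same 2 pools. Where a miRNA was not well above background on any array of a group, the fold is a lower bound, taken against the mean over that group's arrays of the higher of the lowest level among probes well above background and the miRNA's own. Confidence intervals are at 95 percent.

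The 19 lists of miRNAs fixed before the data were examined were the miR-200 family, other epithelial, stromal and mesenchymal, p53-induced, Met-targeting, miR-17-92 and paralogs, let-7 family, tumour-associated, miR-29 and miR-30 families, miR-15 and miR-16 families, Dlk1-Dio3 cluster, pluripotency clusters, leukocyte, erythroid, endothelial, muscle, adipose, neural and liver. Lists were tested with fry, whose p tests whether members move on balance one way, with adjustment over the lists of a comparison. The alternatives were camera with a preset correlation of 0.01 and camera with an estimated correlation. Camera asks another question, whether members move more than the other miRNAs tested. A list that passes with fry and not with camera is therefore not shown to be unchanged. The miRNAs named were the 10 with the largest change in each direction past the threshold, at most 3 of them from the Dlk1-Dio3 cluster, the members of the lists, and for the F-test the 10 with the smallest p.

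The alternatives changed 1 choice at a time, apart from the exceptions named below. They were normexp background correction with an offset of 50, the percentile over all mouse probes, quantile normalisation, the summed signal per miRNA, RMA-type values, the authors' table, the brightest probe, a floor 4 times lower or 2 times higher, no detection filter, only miRNAs detected on all arrays, slide or scan date as a block, eBayes with trend and robust, tumours of 1 title number averaged, parity or histology as a covariate, only the 2 groups compared, for spindloid tumours no genotype covariate or the intermediate tumours left out, and each array left out. The mean spot signal was not used here, so normexp and the RMA-type values started from the median signal, a second change. The covariates of parity and histology limited the fit to tumours that state them. Where single miRNAs of spindloid and other tumours were compared, Trp53 tumours 2 and 3 were averaged. Trp53 tumours 4 and 8 were kept apart there, as only tumour 8 was spindloid. The authors' table had 25 columns and each belonged to a sample. The arrays lay on 5 slides scanned on 3 dates, with tumours of all 3 genotypes on every slide and the normal pools on slides 1 and 3.

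The model was tested on simulated data with independent noise at the spread of these arrays, in 10 repeats with 60 of 330 miRNAs changed. For tumours against normal, 56.3 percent of 2-fold and 86.3 percent of 4-fold changes were recovered. For Met, MetTrp53 and Trp53 against normal the shares were 46.3 and 80.3, 52 and 82.3, and 57 and 83.3 percent. For MetTrp53 against Met the shares were 74.3 and 96.3 percent, for MetTrp53 against Trp53 78 and 95.3 percent, for Met against Trp53 71.3 and 95.3 percent, for the F-test 76.7 and 94.3 percent, and for spindloid against other pathology 74.3 and 94.3 percent. The simulated values had no floor and no correlation between miRNAs, so these shares may not hold for the real arrays. A comparison without calls is therefore not shown to lack 4-fold changes. Figures and summaries were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.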

Results

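The series measured miRNA levels in mouse mammary tumours of 3 genotypes and in normal mammary gland, on 25 one-colour arrays. There were 2 normal pools, 1 from multiparous and 1 from nulliparous mice, 7 Met tumours, 8 MetTrp53 tumours and 8 Trp53 tumours. Met is a receptor tyrosine kinase and Trp53 encodes the tumour suppressor p53. Pathology was stated for 22 tumours. Spindloid tumours numbered 1 among Met, 3 among MetTrp53 and 3 among Trp53, and tumours called intermediate numbered 1 among MetTrp53 and 2 among Trp53. Multiparous mice gave 6 of the Met tumours, 2 of the MetTrp53 tumours and 2 of the Trp53 tumours. The 2 normal pools correlated at r = 0.98 across miRNAs, which are not independent replicates, and the lowest r between any arrays was 0.67.

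Muscle miRNAs were far lower in the tumours than in the normal pools. The level of miR-133b-3p, a miRNA of skeletal and heart muscle, fell by 7.78 on the log2 scale (SE 1.65, limma adjusted p = 0.00165), miR-133a-3p fell by 7.08 (SE 1.34) and miR-1a-3p fell by 6.86 (SE 1.28), and each was lower in all 23 tumours than in both pools. In 16 tumours none of the 3 was well above background, so the size of these differences rests on the floor: over 7 scalings that of miR-133b-3p ran from -9.98 to -6.01 and that of miR-1a-3p from -9.39 to -5.04. The level of miR-378-3p, a member of the adipose list, fell by 3.50 (SE 0.44) and that of the endothelial miR-126-3p by 1.71 (SE 0.54). Whether the fall of miR-378-3p reflects fat or muscle tissue was not tested. Higher in tumours were miR-21-5p, widely described as raised in cancer, by 2.12 (SE 0.66, above both pools in 21 of 23 tumours), and miR-18a-5p of the proliferation-linked miR-17-92 cluster, by 2.01 (SE 0.57, 23 of 23). The level of miR-18a-5p in the pools, 3.62, lay near the floor, and over the scalings its rise ran from 1.13 to 3.23.

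Of 330 miRNAs tested, 43 passed the threshold, 16 higher and 27 lower, and 30 of them changed at least 2-fold. With slide as a block 42 were called, with normexp 27 and over miRNAs detected on all arrays 26. In 3 of the lower ones no tumour array was well above background: miR-29c-5p was at least 2-fold lower (limma adjusted p = 2.05e-12), miR-499-5p at least 1.15-fold (limma adjusted p = 0.000102) and miR-486-3p at least 1.04-fold (limma adjusted p = 0.0466). Their tumour levels lay at or near the floor, which leaves little spread between tumours, so these p-values rest on the floor. With no tumour array well above background they could hardly come out higher, so their direction carries no weight. The median change of miRNAs detected on all arrays was 0.32 on the log2 scale, and it was 0.10 with the percentile taken over all mouse probes, where 7 were called higher and 37 lower. Set against that median of 0.32, miR-21-5p was higher by 1.80, miR-18a-5p by 1.69 and miR-15b-5p by 1.08, while miR-378-3p stood at -3.82 and miR-143-3p at -2.50.

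Among the fixed lists, all 5 muscle members fell (fry adjusted p = 1.64e-05; adjusted p = 0.103 with an estimated correlation). Of these, miR-499-5p was not well above background on any tumour array, so it could hardly have come out higher in tumours. In the adipose list 2 of 4 fell, or 3 adjusted over the list alone (fry adjusted p = 5.17e-05; adjusted p = 0.103 with an estimated correlation). The 2 were miR-378-3p and miR-365-3p, and miR-193b-3p at -2.11 (SE 0.91) passed over the list alone. Both endothelial members fell (fry adjusted p = 0.000185; adjusted p = 0.19 with an estimated correlation), with miR-126-5p at -0.37 (SE 0.07), a direction that turned to 0.14 with normexp, under which the list had an adjusted p of 0.264. The called miRNAs miR-486-3p and miR-676-3p also turned, to 0.10 and 0.09. Of the 10 miR-17-92 members and paralogs, 5 rose, and 9 adjusted over the list alone (fry adjusted p = 0.00833; adjusted p = 0.466 with an estimated correlation), among them miR-19b-3p at 1.60 (SE 0.40) and miR-20a-5p at 1.58 (SE 0.39). Of 6 tumour-associated miRNAs, 1 rose, and 3 adjusted over the list alone (fry adjusted p = 0.013; adjusted p = 0.466 with an estimated correlation). These shifts held their sign on both slides that carried a pool: the muscle list mean was -4.83 on slide 1 and -5.53 on slide 3, the adipose mean -1.84 and -1.19, the endothelial mean -1.20 and -0.93, the miR-17-92 mean 1.06 and 1.35, and the tumour-associated mean 2.01 and 1.99. With slide as a block their fry adjusted p-values were 0.000261, 0.000261, 0.000454, 0.0118 and 0.0658.

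In the stromal and mesenchymal list 3 of 11 fell, and 4 adjusted over the list alone: miR-10b-5p at -2.43 (SE 0.72), miR-143-3p at -2.18 (SE 0.49) and miR-145-5p at -1.74 (SE 0.22) were the 3, and the list did not pass (fry adjusted p = 0.0542). In the miR-29 and miR-30 families miR-29c-3p was 1 of 8 that fell, at -1.87 (SE 0.39, fry adjusted p = 0.066 for the list). With camera at a preset correlation these 2 lists passed (adjusted p = 0.0102 and 0.0249), and with an estimated correlation neither did (adjusted p = 0.466 for both). The miR-200 family and the other epithelial list had 0 of 5 and 0 of 5 members called by limma (fry adjusted p = 0.832 for both). Single members passed in 4 further lists: miR-107-3p of the p53-induced list at -1.56 (SE 0.30), let-7e-5p of the let-7 family at 1.10 (SE 0.27), miR-15b-5p of the miR-15 and miR-16 families at 1.40 (SE 0.22), and miR-128-3p of the neural list at -1.16 (SE 0.26). The Met-targeting list had 2 of 7 lower, miR-1a-3p and miR-206-3p, which are also muscle members. Fry adjusted p-values of these 5 lists were 0.756, 0.885, 0.385, 0.653 and 0.272. No member was called by limma among 11 of the Dlk1-Dio3 cluster, 7 of the leukocyte list and 2 of the erythroid list, and their fry adjusted p-values were 0.733, 0.885 and 0.756. The pluripotency list had 1 member tested, which was not called, and the liver list had 0.

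With only 2 pools, single pools moved the count: 19 miRNAs were called without normal pool 1 and 27 without normal pool 2. Without them in turn, the fry adjusted p was 0.116 and 0.0559 for the miR-17-92 list and 0.191 and 0.0559 for the tumour-associated list.

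**Figure D1:**
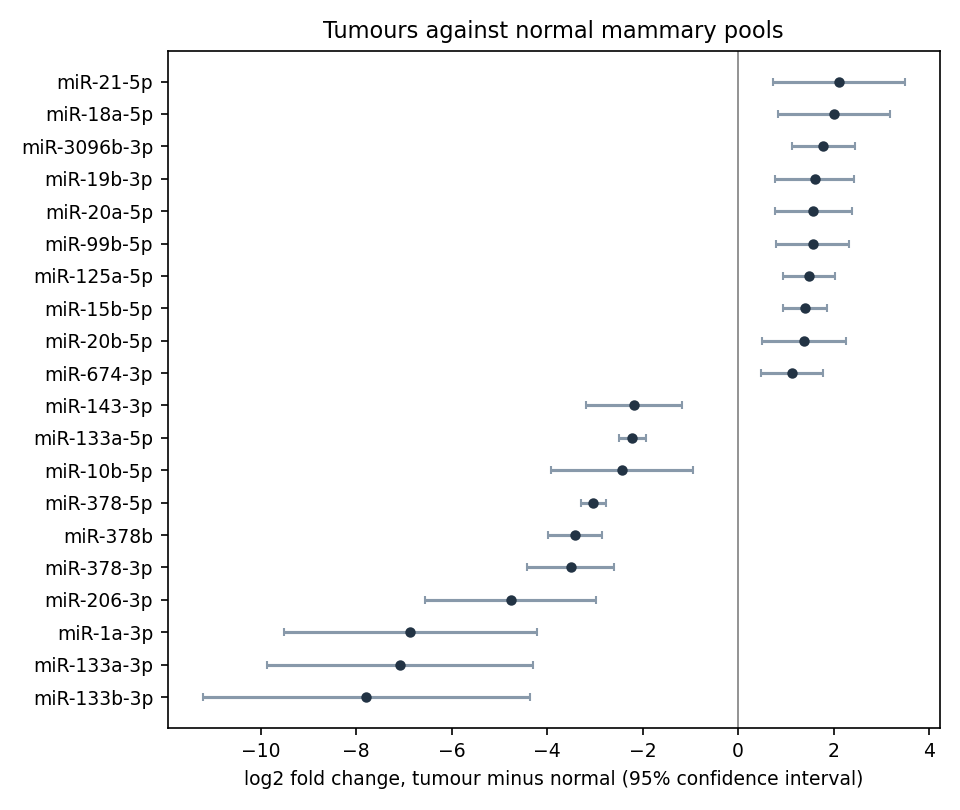
Log2 fold change of the 10 miRNAs with the largest rise and the 10 with the largest fall between 23 tumours and 2 normal pools, with the miRNA on the vertical axis and bars for the 95 percent confidence interval. The muscle miRNA miR-133b-3p lies lowest at -7.78 and miR-21-5p highest at 2.12.

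Each genotype was also set against the normal pools. In Met tumours miR-210-3p, a hypoxia-linked miRNA, rose by 2.60 (SE 0.83, n = 7, limma adjusted p = 0.0412, above both pools in 7 of 7) and miR-34a-5p, a p53 target, rose by 1.62 (SE 0.47, adjusted p = 0.0244, 7 of 7), while miR-107-3p of the same p53-induced list fell by 1.74 (SE 0.33; fry adjusted p = 0.773 for the list). In MetTrp53 tumours miR-31-5p rose by 5.03 (SE 1.41, n = 8, limma adjusted p = 0.0173, above both pools in 8 of 8) and miR-21-5p by 2.66 (SE 0.71). In Trp53 tumours miR-31-5p rose by 4.31 (SE 1.41, n = 8, limma adjusted p = 0.0482, above both pools in 7 of 8), miR-221-3p by 3.06 (SE 0.96) and miR-222-3p by 2.60 (SE 0.85). The value of miR-31-5p in Met tumours was 1.51 (SE 1.43, adjusted p = 0.578).

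Counts were 40 miRNAs for Met (12 higher, 28 lower), 43 for MetTrp53 (16 higher, 27 lower) and 39 for Trp53 (14 higher, 25 lower). With the percentile over all mouse probes the splits were 4 higher and 33 lower, 5 and 39, and 8 and 27. The muscle list had 5 of 5 members lower in each genotype (fry adjusted p = 5.5e-05, 2.89e-05 and 6.96e-05; adjusted p = 0.107, 0.0876 and 0.132 with an estimated correlation). The adipose list had 2 of 4 lower in each (fry adjusted p = 0.000564, 5.33e-05 and 0.000158; adjusted p = 0.138, 0.0876 and 0.132 with an estimated correlation). Of the 2 endothelial members, 2, 1 and 1 were lower (fry adjusted p = 0.000289, 0.000491 and 0.000977; adjusted p = 0.138, 0.269 and 0.29 with an estimated correlation). The miR-17-92 list had 5, 4 and 3 of 10 members higher, or 9, 8 and 6 adjusted over the list alone, with fry adjusted p = 0.00582, 0.0116 and 0.0325 (adjusted p = 0.375, 0.483 and 0.498 with an estimated correlation). The tumour-associated list had 1, 2 and 4 of 6 members higher, or 1, 5 and 5 adjusted over the list alone, with fry adjusted p = 0.425, 0.00723 and 0.00292 (adjusted p = 0.931, 0.483 and 0.29 with an estimated correlation). Against the same pools, the stromal and mesenchymal list had 3, 4 and 2 of 11 members lower, or 3, 4 and 3 adjusted over the list alone, with fry adjusted p = 0.0381, 0.0665 and 0.174 (adjusted p = 0.38, 0.519 and 0.757 with an estimated correlation). The call in Met was lost with normexp (0.161), the summed signal (0.0841), the authors' table (0.0681) and without pool 1 (0.0718) or pool 2 (0.416). The miR-29 and miR-30 families had 1 of 8 members lower in each, or 1, 1 and 5 adjusted over the list alone, with fry adjusted p = 0.554, 0.0539 and 0.0325 (adjusted p = 0.931, 0.483 and 0.476 with an estimated correlation). The call in Trp53 was lost with slide (0.0885) or scan date (0.0655) as a block, quantile normalisation (0.0676), normexp (0.183) and without pool 1 (0.201) or pool 2 (0.127).

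With slide as a block the miR-17-92 list had fry adjusted p = 0.00737, 0.0252 and 0.0317 in Met, MetTrp53 and Trp53, and with scan date as a block 0.0182, 0.0353 and 0.0655, so the call in Trp53 was lost with the latter. Without pool 1 it had 0.0718, 0.116 and 0.201, and without pool 2 it had 0.0626 in MetTrp53 and 0.127 in Trp53. The tumour-associated list had 0.0329 in MetTrp53 and 0.0152 in Trp53 with slide as a block, and 0.116 and 0.0775 without pool 1. The endothelial list was lost with normexp (0.135, 0.222 and 0.482), and in Trp53 also with the summed signal (0.0899) and without pool 1 (0.0501). The adipose list in Met had 0.0542 without pool 1. Without normal pool 1 the counts were 12, 22 and 20, and without normal pool 2 they were 21, 28 and 25. In a model of only the 2 groups, Met against normal gave 19.

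Met and Trp53 tumours, which carry 1 alteration each, differed in single miRNAs, among them 3 of the 5 tested miR-200 family members. In Met tumours miR-200c-3p, which represses the Zeb transcription factors, was higher by 4.41 on the log2 scale (SE 1.19, limma adjusted p = 0.0225, 7 against 8 tumours, 3 Met tumours above all Trp53 tumours), miR-148a-3p by 3.55 (SE 0.68), miR-141-3p by 3.39 (SE 0.85) and miR-146b-5p by 3.24 (SE 0.66). The size for miR-141-3p rests on the floor, as 1 of 8 Trp53 arrays had it above background. That for miR-200c-3p rests on it in part, as Trp53 tumours other than tumour 3 lay between 3.62 and 4.90. Lower in Met tumours were miR-221-3p at -2.94 (SE 0.63), miR-222-3p at -2.41 (SE 0.55) and miR-199b-5p, a miRNA of mesenchymal cells, at -2.12 (SE 0.67). All 7 Met tumours lay below all 8 Trp53 tumours in miR-125a-5p, at -1.11 (SE 0.19). The p53 target miR-34a-5p was higher in Met tumours by 1.41 (SE 0.31), the 1 of 6 members of the p53-induced list that was called (3 of 6 had values below 0; fry adjusted p = 0.938).

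Of 330 miRNAs 30 passed, 16 higher and 14 lower, and 19 of them differed at least 2-fold. The count was 49 with the authors' table and 201 with no detection filter. The split was 10 higher and 15 lower with the percentile over all mouse probes and 9 and 15 with quantile normalisation. In the miR-200 family 3 of 5 members were higher, and 5 adjusted over the list alone (fry adjusted p = 0.0234; adjusted p = 0.737 with an estimated correlation). That call was lost with normexp (0.0555, mean change 1.97). Of 6 tumour-associated miRNAs 2 were lower, and 4 adjusted over the list alone (fry adjusted p = 0.0234; adjusted p = 0.733 with an estimated correlation). In the miR-29 and miR-30 families 3 of 8 were higher, namely miR-30a-5p at 2.38 (SE 0.54), miR-30b-5p at 0.94 (SE 0.26) and miR-30c-5p at 1.57 (SE 0.47), and the list did not pass (fry adjusted p = 0.172). The other epithelial list had 0 of 5 called, and 3 higher adjusted over the list alone (fry adjusted p = 0.054), and the stromal and mesenchymal list had 1 of 11 lower, or 2 higher and 4 lower adjusted over the list alone (fry adjusted p = 0.543). Called members also stood in the leukocyte list (miR-146b-5p, named above, higher and miR-223-3p at -1.61, SE 0.50), the let-7 family (let-7e-5p at -0.90, SE 0.19), the miR-15 and miR-16 families (miR-16-5p at -0.55, SE 0.14) and the Met-targeting list (miR-34a-5p). Fry adjusted p-values of these lists were 0.647, 0.543, 0.609 and 0.838. With camera at a preset correlation the other epithelial list also passed (adjusted p = 0.0217), and with an estimated correlation it did not (adjusted p = 0.787). Within slides 1 to 5 the miR-200 mean difference was 4.32, 0.15, 4.56, 5.17 and 4.91, and the tumour-associated one was -2.17, -0.08, -2.22, -2.52 and -2.48. The single spindloid Met tumour lay on slide 2, as did Trp53 tumour 3, whose miR-200 mean of 8.41 was the highest of the Trp53 tumours. With slide as a block the fry adjusted p was 0.039 for both lists and 28 miRNAs were called.

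The groups also differed in pathology and parity. In the 19 tumours that state parity 11 miRNAs were called without the covariate, an alternative chosen after the data were seen, and 6 with it. Their fry adjusted p was 0.258 for the miR-200 family (mean difference 3.06) and 0.106 for the tumour-associated list (-1.75) without the covariate, and 0.622 (2.62) and 0.0952 (-2.07) with it, so both calls were lost with the tumours left out. With spindloid and intermediate pathology as covariates, in tumours with a stated pathology, 2 were called, and the median change of the 30 miRNAs went from 1.23 (median SE 0.286) to 1.03 (median SE 0.325). With such tumours left out limma called 0 (31 at an unadjusted p under 0.05), at a median change of 1.05 and a median SE of 0.444. Both alternatives were chosen after the data were seen. Without Met tumour 2, the spindloid one, 62 were called, without Met tumour 3 there were 18 and without Met tumour 6 there were 19.

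**Figure D2:**
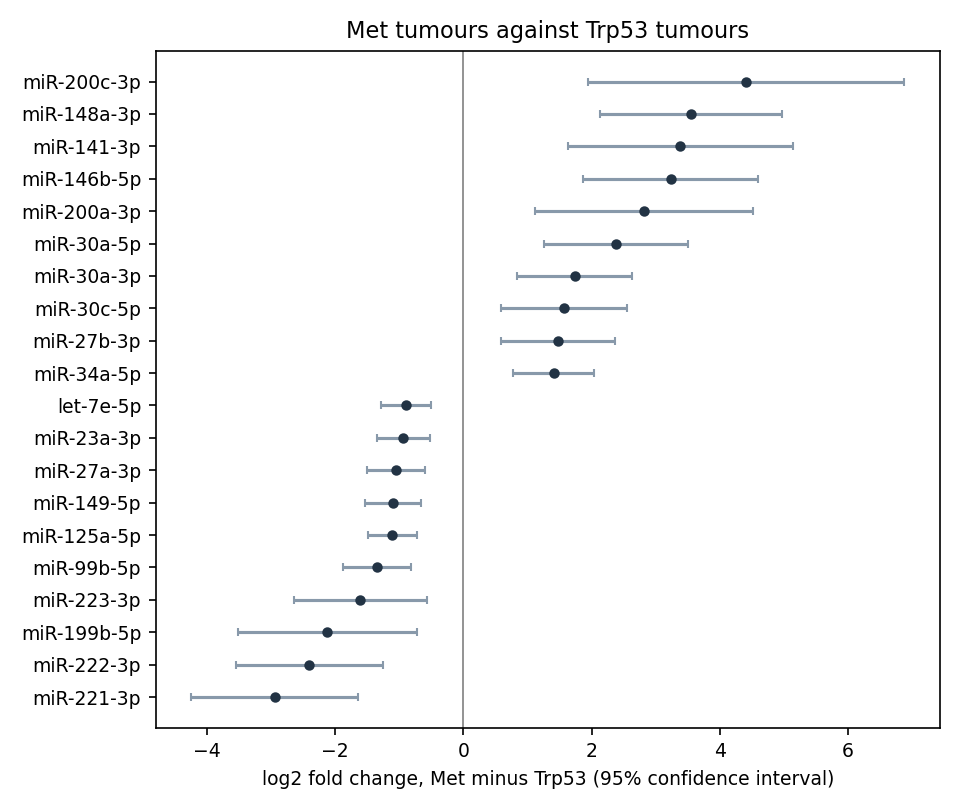
Log2 fold change between 7 Met and 8 Trp53 tumours of the 10 miRNAs with the largest change in each direction, with the miRNA on the vertical axis and bars for the 95 percent confidence interval. Values run from -2.94 for miR-221-3p to 4.41 for miR-200c-3p.

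MetTrp53 tumours carry a deletion of a Trp53 allele beside the transgene of the Met tumours, but these groups also differ in parity and pathology. Of the Met tumours 0 were stated to be from nulliparous mice, against 6 of the MetTrp53 tumours. Spindloid tumours numbered 1 in Met and 3 in MetTrp53, which also had 1 intermediate tumour. The differences below therefore cannot be assigned to the Trp53 allele apart from parity and pathology. The largest measured differences of the 330 miRNAs were 3.52 for miR-31-5p (SE 0.92, limma adjusted p = 0.065), -3.32 for miR-200c-3p (SE 1.19), -2.71 for miR-200b-3p (SE 1.14), -2.63 for miR-429-3p (SE 1.06) and -2.57 for miR-141-3p (SE 0.85). The value of miR-30a-5p was -2.17 (SE 0.54) and that of miR-34a-5p was -1.20 (SE 0.31). None passed: limma called 0 of 330 miRNAs, with 60 at an unadjusted p under 0.05. All 5 miR-200 members were lower adjusted over the list alone, while the list did not pass (fry adjusted p = 0.117), and 4 of 6 tumour-associated miRNAs were higher adjusted over the list alone (fry adjusted p = 0.0993). With camera at a preset correlation the miR-200 family (adjusted p = 0.00272), the tumour-associated list (0.00543) and the Dlk1-Dio3 cluster (0.00543) passed, and with an estimated correlation none did (adjusted p = 0.74, 0.74 and 0.826). The count rested on single tumours, with 41 called without Met tumour 2, 24 without MetTrp53 tumour 3, 15 without MetTrp53 tumour 5, 10 without Trp53 tumour 3 and 1 without Trp53 tumour 2. It was 16 with the authors' table, 14 with a floor 4 times lower, 13 with the summed signal, 7 over miRNAs detected on all arrays, and 5 with normexp or the brightest probe.

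Between MetTrp53 and Trp53 tumours, with 8 in each group, let-7e-5p differed by -0.61 (SE 0.18, limma adjusted p = 0.188) and miR-125a-5p by -0.57 (SE 0.18, limma adjusted p = 0.188). Limma called 0 of 330 miRNAs, with 23 at an unadjusted p under 0.05, and 0 under every alternative tried, each array left out included. No list passed with fry, where the miR-200 family, with 0 of 5 members called, had an adjusted p of 0.953. With camera at a preset correlation the let-7 family (adjusted p = 0.00421) and the Dlk1-Dio3 cluster (adjusted p = 0.0468) passed, and with an estimated correlation none did.

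A moderated F-test over the 3 tumour genotypes called 19 miRNAs. Its smallest p belonged to miR-125a-5p (F = 18.15, adjusted p = 0.00723), followed by miR-149-5p (F = 14.09), miR-148a-3p (F = 13.86) and miR-99b-5p (F = 13.59). Mean levels of miR-34a-5p were 7.99 ± 0.77 in Met (SD, n = 7), 6.79 ± 0.65 in MetTrp53 (SD, n = 8) and 6.58 ± 0.39 in Trp53 tumours (SD, n = 8). The count was 0 in the tumours that state parity (52 at an unadjusted p under 0.05) and 1 with parity as a covariate there, 0 with both pathologies as covariates (35 at an unadjusted p under 0.05), 50 without Met tumour 2, 33 without MetTrp53 tumour 3, 31 without Met tumour 7 and 11 without Met tumour 3.

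Spindloid tumours, whose cells are spindle-shaped, had low miR-200 levels. The mean level of the 5 family members was 3.84 ± 0.38 in spindloid tumours (SD, n = 7), close to the floor of 3.62, 3.83 ± 0.36 in intermediate ones (SD, n = 3) and 7.85 ± 1.73 in tumours of other stated pathology (SD, n = 12). Low levels were not limited to these histologies, as Trp53 tumour 4, an adenocarcinoma, lay at 3.71. By genotype the mean level was 8.04 ± 2.04 in Met (SD, n = 7), 5.35 ± 2.18 in MetTrp53 (SD, n = 8) and 4.65 ± 1.76 in Trp53 tumours (SD, n = 8), against 6.53 ± 0.07 in the normal pools (SD, n = 2). With genotype as a covariate and the intermediate tumours among the others, miR-200b-3p differed by -3.14 (SE 0.83), miR-200c-3p by -3.08 (SE 0.91) and miR-205-5p, a basal epithelial miRNA, by -2.23 (SE 0.72).

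No single miRNA passed: limma called 0 of 330, with 41 at an unadjusted p under 0.05. As lists, the miR-200 family was lower (5 of 5 members adjusted over the list alone; fry adjusted p = 0.0408; adjusted p = 0.177 with an estimated correlation), as was the other epithelial list (4 of 5 adjusted over the list alone; fry adjusted p = 0.0453; adjusted p = 0.177 with an estimated correlation). The miR-200 difference within slides 1 to 5 was -2.81, -3.36, -3.32, -3.13 and -4.52, and that of the other epithelial list was -1.35, -1.21, -2.37, -1.63 and -2.09. Both calls were lost with slide as a block (0.0553 for each), with scan date as a block (0.0742 and 0.0762) and with the tumours of 1 title number averaged (0.0605 and 0.0739). The other epithelial list was also lost with the summed signal (0.058). The stromal and mesenchymal mean was 7.08 ± 0.59 in spindloid tumours (SD, n = 7) and 6.25 ± 0.71 in tumours of neither spindloid nor intermediate pathology (SD, n = 12). Between spindloid tumours and all 15 others the list had a fry adjusted p of 0.337. With camera at a preset correlation it passed (adjusted p = 0.00431), as did the Dlk1-Dio3 cluster (0.00272), the tumour-associated list (0.000808) and the miR-17-92 list (3.8e-05), and with an estimated correlation none did (0.48, 0.48, 0.177 and 0.306). With the intermediate tumours left out 16 miRNAs were called, 4 higher and 12 lower, among them miR-200b-3p at -4.16 (SE 0.68) and miR-96-5p at -2.32 (SE 0.51). With the intermediate tumours kept among the others, the count went from 0 to 1 without Trp53 tumour 1.

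**Figure D3:**
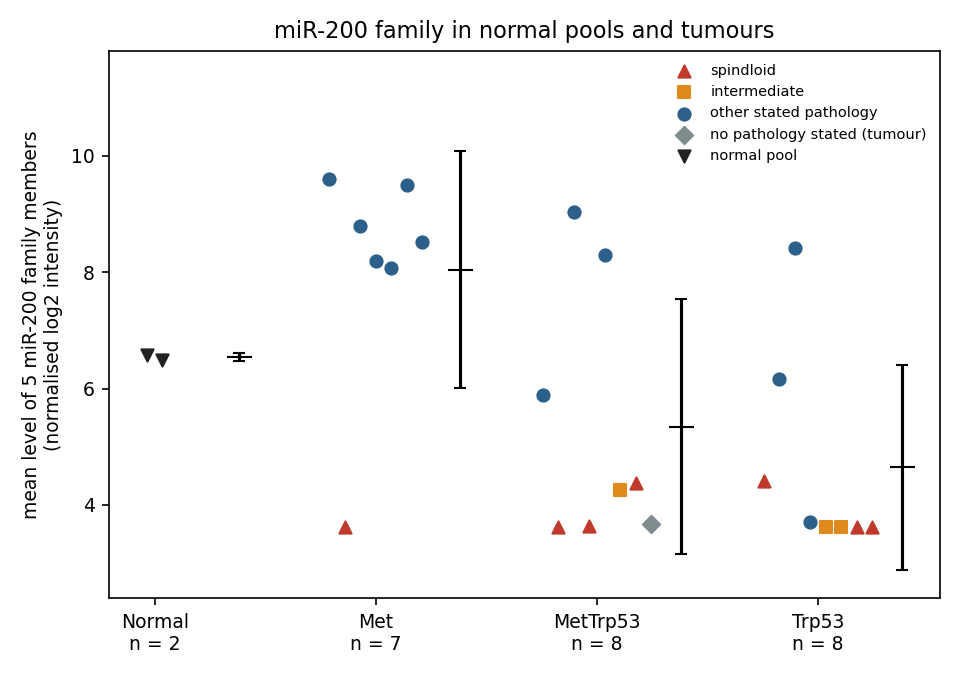
Mean normalised log2 intensity of 5 miR-200 family members in each normal pool and tumour, by group, with symbols for pathology and a bar for the group mean and SD. Spindloid and intermediate tumours lie between the floor of 3.62 and 4.41. Trp53 tumour 4, an adenocarcinoma, at 3.71 and MetTrp53 tumour 8, with no stated pathology, at 3.68 also lie there. Met tumour 2 at 3.62 stands apart from the other Met tumours, which lie between 8.07 and 9.60.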

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

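Of the tests in this part, those of scaling, muscle tissue, slides, epithelial cell share and weaker arrays were chosen after the result was seen, and so was the standard error set beside the histology and parity shares and beside the number of detected miRNAs. A first test of muscle tissue, a correlation over all tumours, had met its bound for that cause and was set aside, because the tumours fall into those with and without muscle signal. The muscle test was later limited to tumours well above background and given an error, and the scaling test was moved from called members to all members of the lists.

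Muscle, adipose and endothelial miRNAs were lower in tumours than in the normal pools, with 9 members called. Scaling alone is argued against for each list. Over 7 scalings the change of all tested members, set against the median of miRNAs detected on all arrays, lay below 0 by over 2 standard errors each time. Where it did so by the fewest, it was -7.60 (SE 1.75) for muscle, -1.71 (SE 0.32) for adipose and -1.57 (SE 0.46) for endothelial. One unusual pool is argued against too, as 7 of the 9 stayed called without the pool whose loss cost more, though miR-126-3p was lost without either pool and miR-365-3p without pool 1. Muscle tissue in the samples stays open: in the 6 tumours with miR-1a-3p, miR-133a-3p and miR-133b-3p all well above background their differences departed from those of the pools by up to 0.994, near the bound of 1 within the error of the pools (SE 0.221). That largest departure was in Met tumour 5, whose muscle mean of 4.03 lay near the floor. Loss of muscle, fat and vessel tissue from tumours, a biological difference between tumour and gland, was not tested apart from the amount of muscle tissue.

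The 30 miRNAs that differ between Met and Trp53 tumours outnumbered every other of 100 splits of these tumours. Only 1 split, the real one, reached 30, which argues against chance. The highest other split gave 29, so chance is not excluded. With slide as a block 27 of the calls remained, which argues against slides. With parity as a covariate the median change kept 0.985 of its size in the 19 tumours that state it (jackknife SE 0.18). No Met tumour was stated to be from a nulliparous mouse, so the effect of parity was estimated within MetTrp53 and Trp53 tumours. This argues against parity as the whole cause only if parity acts alike in Met tumours, which could not be tested. The mix of spindloid and intermediate histology cannot be told apart from genotype, since the median kept 0.834 of its size (jackknife SE 0.203), near the bound of 0.75 within that error, and calls went to 2 as the median SE went from 0.286 to 0.325. In 6 Met and 3 Trp53 tumours of neither histology limma called 0 miRNAs, with 31 at an unadjusted p under 0.05, while the median change was 1.05 (median SE 0.444). These miRNAs were chosen with the same tumours, so this decides nothing between genotype and histology.

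With genotype as a covariate, the miR-200 family was lower in spindloid and intermediate tumours by -3.42 (SE 0.56, 10 against 12 tumours). The plain means were 3.84 and 7.85. Counting intermediate with spindloid tumours was chosen after the data were seen. An equal rise of stromal, immune and vessel cells had been set as the mark of a lower share of epithelial cells. With the same covariate the stromal list changed by 0.75 (SE 0.31), the endothelial list by 0.41 (SE 0.18) and the leukocyte list by -0.09 (SE 0.28). Stromal and leukocyte changes differed by 3.28 standard errors, stromal and endothelial ones by 1.74. A lower epithelial share need not raise these cells alike, so the test cannot decide on it. Weaker arrays are argued against, because 40 other miRNAs of the brightness of the miR-200 members changed by -0.244 on average (SE 0.072), and 4 of them by at least 0.5 of the change of the family. An earlier test of this, the number of detected miRNAs, decided nothing, with 3.1 more on the 10 arrays (SE 11.2, permutation p = 0.787, two-sided). A lower share of epithelial cells stays open, with more stromal cells alone or with others, as does a change within the tumour cells.

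Other splits of the samples gave the following. Between MetTrp53 and Met 60 miRNAs had an unadjusted p under 0.05, the highest other split gave 82 and 5 of 100 gave as many, so chance could not be excluded. Between MetTrp53 and Trp53 it was 23, against 51 and 10 of 100, and chance could not be excluded. Over the 3 genotypes 19 were called, against 2 in the highest other split, and 1 of 100, the real one, reached it, which argues against chance. For spindloid against other histology it was 41, against 68 and 7 of 100, and chance could not be excluded. Once intermediate tumours were left out it was 16 called, against 2, with 1 of 100, which argues against chance. With 100 splits no share under 1 of 100 can be shown.

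Single samples lay far from the others, relative to the range of their group, in 29 of 177 groups of values examined. A chance rate of 1 in 20 groups, or 8.8, does not hold where the others are tied at the floor. In Met tumours miR-133a-5p was flagged at 3.683 against 3.615 in the others, and miR-378-5p at 3.854 against 3.615 to 3.616. The 29 can therefore not be set against 8.8. Many of the flagged values come from the same tumours and from related miRNAs. Met tumour 2, the spindloid one, had a miR-200 mean of 3.62, another epithelial mean of 3.93, miR-200c-3p, miR-141-3p and miR-200a-3p at 3.62, miR-148a-3p at 6.20, miR-222-3p at 6.09 and miR-149-5p at 4.42. Trp53 tumour 3 had miR-200c-3p at 9.77, miR-141-3p at 7.35, miR-146b-5p at 8.12 and miR-30a-3p at 5.37. MetTrp53 tumour 5 had a muscle mean of 7.52, miR-133b-3p at 9.80, miR-133a-3p at 8.83, miR-1a-3p at 8.96, miR-206-3p at 6.37 and miR-133a-5p at 4.195. Met tumour 4 had miR-133a-3p at 7.69, miR-1a-3p at 7.69 and miR-133a-5p at 3.68. Trp53 tumour 1 had miR-378-5p at 4.12 and miR-133a-5p at 4.25. Met tumour 5 had a leukocyte mean of 8.07, a Dlk1-Dio3 mean of 4.36 and miR-378-5p at 3.85. Trp53 tumour 2 had a stromal mean of 5.90. Met tumour 3 had 2384 spots marked as outliers by the scanner software, against 1646 to 1885 in the other Met tumours. Met tumour 1 had a log2 scaling percentile of 8.11, against 8.98 to 9.52.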

How the results depend on the processing

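Each alternative changed 1 choice, except that the covariates also limit the tumours to those that state them, and that normexp and the RMA-type values also start from the median signal. The values are numbers of miRNAs called at an adjusted p under 0.05. The alternatives chosen after the data were seen were both histologies as covariates, tumours of either histology left out, tumours with a stated parity without the covariate, and intermediate tumours counted with spindloid. The cause of a moved count was not tested unless said. Replicate numbers were given in accession order, so no paired analysis was possible because they pair nothing.

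Tumours against normal gave 43, but 27 with normexp and 26 over miRNAs detected on all arrays. With 1 array left out it lay between 19 and 45. Met against normal gave 40, but 26, 25 and, with only the 2 groups compared, 19, and 12 to 45 with 1 array left out. MetTrp53 against normal gave 43, and 22 to 50 with 1 array left out. Trp53 against normal gave 39, but 25 with normexp and 20 over miRNAs detected on all arrays, and 20 to 43 with 1 array left out. The lowest of each came without normal pool 1.

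MetTrp53 against Met gave 0, but 5 with normexp, 13 with the summed signal, 16 with the authors' table, 5 with the brightest probe, 14 with a floor 4 times lower and 7 over miRNAs detected on all arrays. With 1 array left out it lay between 0 and 41. MetTrp53 against Trp53 gave 0 under every alternative and with any array left out.

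Met against Trp53 gave 30, but 49 with the authors' table, 201 with no detection filter, 6 with parity as a covariate in the tumours that state it and 19 with spindloid histology as a covariate. With both histologies as covariates it gave 2, with such tumours left out 0, and in tumours with a stated parity without the covariate 11. With 1 array left out it lay between 18 and 62.

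The F-test over genotypes gave 19, but 31 with the authors' table, 32 with the lower floor, about 1.9e+02 with no detection filter, 12 with slide as a block, 1 with parity and 10 with spindloid histology as a covariate. It gave 0 with both histologies as covariates, 0 with such tumours left out and 0 in tumours with a stated parity. With 1 array left out it lay between 11 and 50.

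Spindloid against other histology gave 0, but 6 with normexp, 1 with the summed signal, 1 with the authors' table, 1 with the lower floor, 16 with intermediate tumours left out and 23 with these counted as spindloid. With 1 array left out it lay between 0 and 1.

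The change of miR-126-5p in tumour versus normal reversed to 0.143 with normexp, and that of miR-499-5p in tumour versus normal became 0 with a floor 2 times higher. With tumours of 1 title number averaged, the spindloid difference had a fry adjusted p of 0.0605 for the miR-200 family and 0.0739 for the other epithelial list. The stromal list of Met against normal had 0.161 with normexp, 0.0718 without normal pool 1 and 0.416 without normal pool 2.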

Other observations

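The test of the difference between genotypes, with and without intermediate tumours, was chosen after the result was seen, and the cluster levels of Trp53 tumour 2 were picked out after their values were seen.

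The miR-200 family comes from 2 gene clusters, 1 with miR-200a, miR-200b and miR-429 and 1 with miR-200c and miR-141. In Trp53 tumour 2, an adenocarcinoma, the mean level of the first cluster was 7.55 and that of the second 4.08, a difference of 3.47 on the log2 scale. In the 9 other tumours with a first-cluster mean above 6 this difference lay between -0.75 and -0.02. Trp53 tumour 4, also an adenocarcinoma, had means of 3.73 and 3.67.

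MiRNAs of neighbouring genes may vary together among tumours of a genotype. Of 330 miRNAs 262 matched 1 gene by name in the RefSeq table used here, and 102 pairs lay within 10000 bases. Their median correlation over 23 tumours, after the genotype means were taken out, was 0.663, against 0.006 for other pairs, a difference of 0.657. The correlations of miR-200b-3p with miR-429-3p and of miR-182-5p with miR-183-5p were 0.995 and 0.982, while 11 pairs lay below 0, the lowest being miR-322-5p with miR-351-3p at -0.359. Probes that bind related sequences were not tested as a cause.

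The miR-200 difference between spindloid and other tumours was -2.99 in MetTrp53 (3 against 4 tumours) and -1.23 in Trp53 (3 against 5), with 1 and 2 intermediate tumours among the others. Their difference of -1.76 (SE 1.85, exact permutation p = 0.245, two-sided) decides nothing at this error. With the intermediate tumours left out the values were -3.86 (3 against 3) and -2.21 (3 against 3), and their difference -1.65 (SE 1.70). A first bound, within 1 standard error of 0, was met and was set aside, because a wide error meets it more easily. Limma called 0 miRNAs for that difference, with 5 at an unadjusted p under 0.05.

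Of 57 viral miRNAs on the arrays, 9 were detected on some tumour array and 8 on a normal array. Among them mcmv-miR-M23-1-5p and mghv-miR-M1-2-3p were detected on 23 tumour arrays and 2 normal arrays. Whether such signals come from viral RNA or from probes that bind other RNA was not tested.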
